A study of Homo sapiens with 6 samples.

How the data were processed

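Gene expression was measured by RNA-seq in 6 libraries of PANC-1 cells, 3 transfected with a control siRNA (si-NC) and 3 with a LINC00261 siRNA (si-LINC00261), and each sample was placed in its group and given its replicate number from its title. The titles do not say whether the numbers 1 to 3 stand for repeats of 1 siRNA or for different siRNAs, and the siRNA sequences are not given in the sources used here. One table held the whole series, with a count and an FPKM value per gene and library. The deposited count columns held whole numbers per gene that were not normalized, per the file headers and the values. The deposited FPKM columns, per the file headers, held fragments per kilobase of transcript scaled to library size. The relative depths that the FPKM values imply differed from the relative totals of the counts by at most 0.109%. HISAT2 2.0.4, Cufflinks 2.1.1 and Cuffdiff are named in the submitters' processing notes, without saying which step each did. How reads were assigned to genes, whether strand was used, and how ribosomal RNA was removed are not given in the sources used here.

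The genome build named in the submitters' processing notes is mm10, a mouse build, but all 46172 gene identifiers in the table were human Ensembl identifiers. Of 45480 genes found in GENCODE release 29 (GRCh38), 43123 (94.8%) had exactly the same start and end, so coordinates are given on GRCh38. The table used here broke off inside its last line: 46173 lines were read, 1 was incomplete and left out, and 17850 of 19951 GENCODE protein-coding genes (89.5%) were listed. Genes beyond that point were not analysed here, and library totals are sums over the listed genes. Every column of sample values was matched to a sample by its title.

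Library totals ranged from 18660668 to 29601994 counts. Genes were kept with edgeR's filterByExpr (minimum count 10), which left 15670, and library sizes were scaled by TMM. Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 under R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. CPM values are counts per 1000000 on TMM-scaled sizes. LINC00261, FOXA2 and MYC were also compared by a two-sided exact permutation test of group means. On counts simulated from these libraries for the same comparison, with 15430 genes tested, the edgeR step recovered 22.4% of 67 genes changed 1.5-fold, 73.1% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, with 4 false calls among 129. Few genes changed in that simulation, so these shares do not carry over to a comparison with 4729 calls. Of the tested genes, 6433 (41.1%) overlapped another listed gene with a mean of at least 10 counts. Without strand information, reads of overlapping and antisense genes cannot be told apart, and the same holds for near-identical copies such as pseudogenes, so values of such genes are uncertain.

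The comparisons, the tests, the 37 gene lists, the rule for naming genes and the first set of alternative settings were chosen before the data were examined. The rule named LINC00261, FOXA2 and MYC, the 10 genes with the highest and the 10 with the lowest log2 fold change, the 5 genes of highest mean level in each direction, and up to 4 members with the smallest p of each list named. Genes chosen for fold change or level had an adjusted p under 0.05, a group mean of at least 1 CPM, no overlap between groups and a symbol not taken from a clone. The lists held 625 symbols, which matched 525 genes of the table. Some of the unmatched symbols were older or newer names of the same gene. Others, such as CDC20, CENPE, LDHA and PFKL, were members absent from the table used here, and these were not tested. Counts of genes per list refer to the measured members only. At least 5 members past the filter were left in 32 lists. Lists were tested with camera of limma 3.58.1 on log2 CPM at a preset correlation of 0.01, adjusted over the 32 lists, beside camera with an estimated correlation and fry. The alternative settings were the replicate number as a block, each library left out in turn, DESeq2's size factors in edgeR, no count filter, at least 50 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2(FPKM + 1) for genes with at least 1 FPKM in 3 libraries, and calls of at least 2-fold. Restricting the test to genes that overlap no other gene, removing each library's trend with transcript GC content and length, and using table totals without TMM joined them after the data had been seen.

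For 11446 tested genes with a GENCODE 3' UTR of at least 50 bases, 15661 words of 7 bases (heptamers) carried by at least 100 genes were compared between carriers and other genes. Each gene was represented by the 3' UTR of a chosen coding transcript, so sites in its other 3' UTRs were not counted. Log2 fold changes were limited to 2 in size and adjusted for UTR length, UTR GC content and mean expression level. The genes were permuted 100 times among genes of like UTR length. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used for these steps and the figures.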

Results

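RNA was sequenced from PANC-1 cells, an established human pancreatic carcinoma cell line, after transfection with a small interfering RNA (siRNA) against LINC00261 or with a control siRNA. An siRNA is a short duplex that directs cleavage of a matching transcript. LINC00261 is a long intergenic non-coding RNA whose gene lies beside FOXA2, which encodes a transcription factor of endoderm and pancreas. The study's title presents it as a suppressor of pancreatic cancer progression. The control group (si-NC) and the LINC00261 group (si-LINC00261) held 3 libraries each. The deposited table gave 23621413, 24372847 and 26318538 counts for si-NC replicates 1 to 3. It gave 25585596, 29601994 and 18660668 counts for si-LINC00261 replicates 1 to 3. Across tested genes, log2 expression correlated with a Pearson r of 0.984 to 0.990 between libraries of a group and 0.973 to 0.980 between groups. The first principal component held 45.8% of the variance and separated the groups. The second held 18.4% and set si-LINC00261 replicate 3 apart from the other 2 libraries of its group. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

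LINC00261 fell in all 3 libraries that received its siRNA, to 34.6% of the control level. Its level was 21.4 ± 0.930 CPM (counts per 1000000, SD, n = 3) in si-NC and 7.41 ± 0.524 CPM (n = 3) in si-LINC00261. In the authors' FPKM these levels were 3.17 ± 0.160 and 1.10 ± 0.0719. The gene (ENSG00000259974) occupies chromosome 20, positions 22547671 to 22578642 of GRCh38, on the minus strand. GENCODE annotates it as a lincRNA with 3 transcripts of 2 to 4 exons. Counts on the gene ran from 481 to 561 in si-NC and from 128 to 223 in si-LINC00261, with no overlap between groups. The log2 fold change was -1.53 (SE 0.08, edgeR adjusted p = 2.18e-04). A two-sided exact permutation test of the group means gave p = 0.1, the smallest value that 3 against 3 libraries allow.

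FOXA2, whose locus lies 2362 bp from that of LINC00261, stood at 31.4 ± 2.16 CPM in si-NC and 36.3 ± 0.444 CPM in si-LINC00261 (SD, n = 3). Its log2 fold change of 0.21 (SE 0.06) missed the threshold narrowly, with an edgeR adjusted p of 0.0524. All 3 si-LINC00261 libraries lay above all 3 si-NC libraries. The adjusted p ranged from 0.0207 to 0.204 over the 16 alternative settings, 6 of which put it past the threshold. MYC, the oncogenic transcription factor, had counts of 35, 173 and 24 in si-NC and 51, 570 and 349 in si-LINC00261. These counts gave MYC a log2 fold change of 2.08 with an SE of 1.00 (edgeR adjusted p = 0.166). With a library left out the value ran from 1.63 (without si-NC replicate 3) to 3.46 (without si-NC replicate 2). None of the 15 alternative settings that tested MYC brought it past the threshold, with adjusted p from 0.0675 to 0.337. MYC was not tested on FPKM, where it did not pass the filter.

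**Figure D1:**
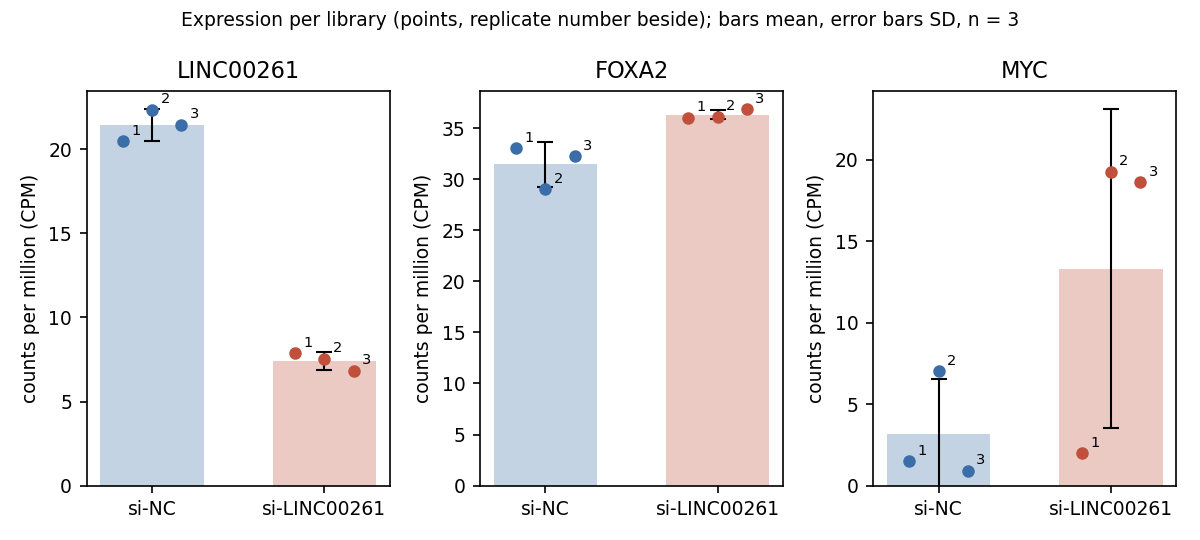
Levels of LINC00261, FOXA2 and MYC in CPM (vertical axes) in each library, with replicate numbers beside the points, bars at the group mean and error bars of 1 SD (n = 3). LINC00261 lay at 20.5 to 22.4 CPM in si-NC and at 6.83 to 7.85 CPM in si-LINC00261, while MYC in si-LINC00261 ran from 2.00 to 19.3 CPM, and its lower error bar in si-NC would pass below 0.

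Several genes that were nearly silent in the control cells rose with the LINC00261 siRNA, and REST, TRIM32 and SAMD12 fell to a small part of their control level. Among the genes that rose were NPC1L1, a cholesterol uptake transporter of the intestine, with a log2 fold change of 3.89 (SE 0.27), and CES1, a carboxylesterase of the liver, with 3.05 (SE 0.39). LEFTY1, a secreted Nodal inhibitor, had a log2 fold change of 2.40 (SE 0.30). REST, a repressor of neuronal genes on chromosome 4 (56907876 to 56935844, GRCh38), dropped from 123 ± 7.38 to 23.4 ± 1.31 CPM (SD, n = 3), a log2 fold change of -2.40 (SE 0.07, edgeR adjusted p = 5.16e-05). TRIM32, an E3 ubiquitin ligase gene on chromosome 9 (116687302 to 116701300, GRCh38), dropped from 33.2 ± 0.840 to 3.84 ± 0.432 CPM (SD, n = 3), a log2 fold change of -3.11 (SE 0.10, edgeR adjusted p = 5.16e-05). In all, 4729 of 15670 tested genes changed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2307 rose and 2422 fell, and 231 rose and 271 fell at least 2-fold. The groups did not overlap at 7391 of the 15670 tested genes (47.2%), where chance gives 10%. An unadjusted p under 0.05 was found for 6520 genes.

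The other genes with the highest fold changes were TGIF2-C20orf24 (6.31 on the log2 scale, SE 0.75), AMIGO3 (5.69, SE 0.32), and YJEFN3 (3.50, SE 0.23). RASL12 (2.86, SE 0.24), TMEM52B (2.29, SE 0.28), IGSF10 (2.22, SE 0.28) and TINCR (2.20, SE 0.22) followed. Most of them stayed low after the rise: NPC1L1 reached 2.06 ± 0.297 CPM, CES1 1.15 ± 0.128 CPM and LEFTY1 1.15 ± 0.147 CPM (SD, n = 3). TINCR reached 7.26 ± 0.703 CPM. More genes had a count above 0 in si-LINC00261 replicates 1 to 3 (23518, 23970 and 24162) than in si-NC replicates 1 to 3 (22463, 22748 and 22678). The numbers of genes with at least 10 counts overlapped between groups (15187 to 16054 and 15376 to 15660). Whether this wider detection bears on the rise of low genes was not tested. The other genes with the lowest fold changes were TMEM56-RWDD3 (-3.65, SE 0.55), NDRG2 (-2.96, SE 0.60), C9orf69 (-2.76, SE 0.78) and SAMD12 (-2.53, SE 0.09). They were followed by TMEM74B (-2.35, SE 0.46), AMPD3, an AMP deaminase (-2.34, SE 0.11), TRAPPC5 (-2.20, SE 0.20) and CYFIP2, a subunit of the actin-regulating WAVE complex (-2.19, SE 0.32). The edgeR adjusted p of the 20 genes chosen for their fold change ranged from 5.16e-05 (REST and TRIM32) to 0.0394 (C9orf69). C9orf69 stood at 5.92, 4.36 and 28.2 CPM in the si-NC libraries. Without si-NC replicate 3 its log2 fold change was -1.43. Its edgeR adjusted p was 0.114, 0.112 and 0.0750 without si-LINC00261 replicate 1, 2 or 3, in a range of 0.00661 to 0.124 over all alternatives. NDRG2 had a log2 fold change of -2.37 without si-LINC00261 replicate 1, and TMEM74B of -3.08 without si-LINC00261 replicate 2. TGIF2-C20orf24 stood at 0, 0 and 0.497 CPM in the si-NC libraries. Without si-NC replicate 3 its fitted log2 fold change was 11.44, a value over a group at 0, so the size of its rise is uncertain. TGIF2-C20orf24 and TMEM56-RWDD3 are readthrough genes that share exons with TGIF2 and C20orf24 and with TMEM56 and RWDD3. Each of AMIGO3 (GMPPB), YJEFN3 (NDUFA13), RASL12 (SLC51B), TMEM52B (OLR1), IGSF10 (MED12L), TRIM32 (ASTN2), NDRG2 (ARHGEF40), TMEM74B (PSMF1) and CYFIP2 (ADAM19) overlaps the gene in parentheses. LEFTY1, SAMD12 and TRAPPC5 overlap genes without a protein product or with clone names. The strand handling of the counts is not given, so the values of all these genes are uncertain.

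**Figure D2:**
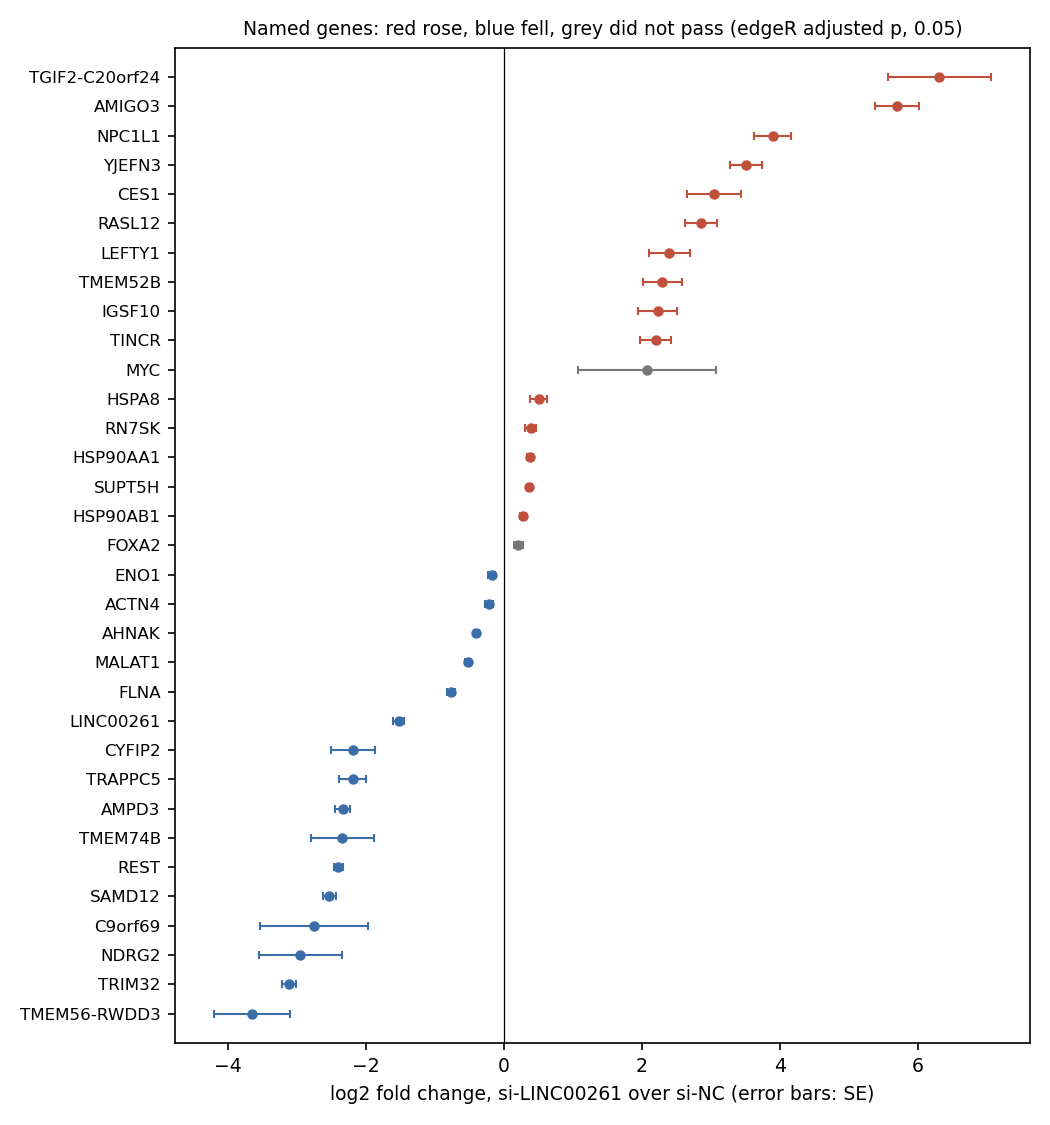
Log2 fold change of si-LINC00261 over si-NC (horizontal axis, n = 3 per group) for 33 named genes (vertical axis), with error bars of 1 SE. The values run from -3.65 for TMEM56-RWDD3 to 6.31 for TGIF2-C20orf24; FOXA2 and MYC are the 2 genes in grey that did not pass the test.

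Among the most abundant transcripts, the chaperone genes HSP90AB1, HSP90AA1 and HSPA8 rose, and MALAT1, FLNA, AHNAK, ACTN4 and ENO1 fell. HSP90AB1 went from 4438 ± 139 to 5341 ± 215 CPM and HSP90AA1 from 1911 ± 64.7 to 2476 ± 72.0 CPM (SD, n = 3). Their log2 fold changes were 0.27 (SE 0.04) and 0.37 (SE 0.04). HSPA8 rose by 0.50 (SE 0.12) on the log2 scale. RN7SK, a small nuclear RNA that holds back the elongation factor P-TEFb, rose by 0.39 (SE 0.08), and SUPT5H, a subunit of the elongation factor DSIF, by 0.36 (SE 0.04). RN7SK lost its call in limma-trend on log2(FPKM + 1), with an adjusted p of 0.0540 and a log2 fold change of 0.39. MALAT1, a nuclear long non-coding RNA, took 2.85%, 2.86% and 2.71% of the counts in si-NC and 1.97%, 1.86% and 2.02% in si-LINC00261. Its log2 fold change was -0.53 (SE 0.04, edgeR adjusted p = 4.95e-04). FLNA, the actin crosslinker filamin A, dropped from 3610 ± 226 to 2124 ± 90.5 CPM (SD, n = 3), a log2 fold change of -0.77 (SE 0.06, edgeR adjusted p = 4.29e-04). AHNAK changed by -0.40 (SE 0.03), ACTN4, an alpha-actinin, by -0.22 (SE 0.06) and ENO1, a glycolytic enolase, by -0.18 (SE 0.05) on the log2 scale. HSPA8 lost its call without any 1 of the si-NC replicates 1, 2 and 3 (edgeR adjusted p = 0.0596, 0.0793 and 0.0622). ENO1 lost it without si-NC replicate 1 or 3 or si-LINC00261 replicate 1 or 2 (0.0842, 0.0881, 0.0512 and 0.0582). ACTN4 lost it without si-NC replicate 1 or 3 or si-LINC00261 replicate 2 or 3 (0.0809, 0.0865, 0.0754 and 0.0756).

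Limma's camera, a test of a gene list against other genes, called 2 lists of cell division genes upward at a preset correlation of 0.01, and neither with an estimated correlation (adjusted p = 0.630 for both). Of 18 measured genes of G2/M and mitosis, 9 rose, 0 fell and 9 did not pass. When adjusted over the list alone, 11 rose and 0 fell. TPX2, a spindle assembly factor, rose by 0.48 (SE 0.03) and TOP2A, a DNA topoisomerase, by 0.35 (SE 0.03) on the log2 scale. The checkpoint kinase gene BUB1 rose by 0.43 (SE 0.04) and the cyclin gene CCNB2 by 0.51 (SE 0.05). The median over the list was 0.26, and camera at the preset correlation gave an adjusted p of 0.00132 over 32 lists. Of 17 genes of G1/S and DNA replication, 9 rose, 1 fell and 7 did not pass, with the same counts of 9 and 1 when adjusted over the list alone. The camera adjusted p was 0.0222. CDC6, a replication licensing factor, rose by 0.38 (SE 0.04), the ribonucleotide reductase gene RRM2 by 0.26 (SE 0.03) and the transcription factor gene E2F1 by 0.51 (SE 0.08). UHRF1, which maintains DNA methylation, changed by -0.56 (SE 0.07).

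Growth genes that MYC is known to activate rose more often than they fell, as did ribosomal protein and heat shock genes. Of 25 MYC-activated growth genes, 8 rose and 3 fell (9 and 3 when adjusted over the list alone), with a median log2 fold change of 0.15. Camera gave an adjusted p of 0.0237, against adjusted p = 0.630 with an estimated correlation. The nucleolar protein genes NOLC1 (0.80, SE 0.04), FBL (0.46, SE 0.06) and BOP1 (0.40, SE 0.05) were among those that rose. The 3 that fell were TFRC, the transferrin receptor gene (-0.40, SE 0.04), and CCND2 (-0.78) and EIF4E (-0.30), the last pair named after their values were seen. Of 20 cytosolic ribosomal protein genes, 8 rose and 0 fell, both over all genes and when adjusted over the list alone. Their median was 0.16 and their camera adjusted p 0.0237, against adjusted p = 0.630 with an estimated correlation. With the GC and length trends removed the call was lost (adjusted p = 0.0793), with a median of 0.13 (SD over genes 0.16), against 0.16 (SD 0.15) before. RPL11 stood at 0.48 (SE 0.07), RPS6 at 0.29 (SE 0.05), RPL19 at 0.29 (SE 0.04) and RPL8 at 0.27 (SE 0.04). Of 12 heat shock genes, 6 rose and 0 fell (7 and 0 when adjusted over the list alone). Their median was 0.20 and their camera adjusted p 0.0222, against adjusted p = 0.630 with an estimated correlation. Among them were HSPB1 at 0.52 (SE 0.08) and DNAJA1 at 0.24 (SE 0.03) beside HSP90AA1 and HSP90AB1.

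Camera at the preset correlation called 3 lists downward: fatty acid synthesis, interferon response, and metastasis and invasion. None of these calls held with an estimated correlation (adjusted p = 0.630 for each). Of 11 fatty acid synthesis genes, 7 fell and 0 rose, both over all genes and when adjusted over the list alone. The median was -0.18 and the camera adjusted p 0.0222, against 0.0572 without si-LINC00261 replicate 1. The stearoyl-CoA desaturase gene SCD dropped from 2509 ± 58.8 to 1831 ± 62.7 CPM (SD, n = 3). Log2 fold changes were -0.45 (SE 0.04) for SCD, -0.49 (SE 0.04) for ELOVL6, -0.51 (SE 0.06) for ACSS2 and -0.40 (SE 0.05) for the fatty acid synthase gene FASN. Of 13 interferon response genes, 6 fell and 1 rose (7 and 1 when adjusted over the list alone). The median was -0.40 and the camera adjusted p 0.0237. This call was lost without si-NC replicate 1 (0.0640) or si-LINC00261 replicate 1 (0.0663) or 3 (0.0850), without a count filter (0.0643), at 50 counts (0.0582) and without overlapping genes (0.0920). The RNA sensor gene DDX58 changed by -0.40 (SE 0.04), ISG15 by -0.62 (SE 0.10), OAS3 by -0.21 (SE 0.04) and IFI6 by -0.84 (SE 0.20). OAS3 lost its call with the replicate block (edgeR adjusted p = 0.0506), and IFI6 without si-NC replicate 1 or 3 or si-LINC00261 replicate 2 or 3 (0.0681, 0.0660, 0.0678 and 0.0538). IRF7, named after its value was seen, was the member that rose (0.49). Of 15 genes of metastasis and invasion, 7 fell and 1 rose (8 and 1 when adjusted over the list alone). The median was -0.40 and the camera adjusted p 0.0421. The call was lost without any 1 of the 6 libraries (camera adjusted p from 0.0601 to 0.0819), with the replicate block (0.0680), without a count filter (0.0646) and without overlapping genes (0.201). The hyaluronan receptor gene CD44 dropped from 1546 ± 12.4 to 917 ± 41.9 CPM (SD, n = 3), a log2 fold change of -0.75 (SE 0.04). The urokinase receptor gene PLAUR (-0.85, SE 0.10) and the integrin gene ITGB4 (-0.60, SE 0.08) also fell. ITGA6, named after its value was seen, rose by 0.11.

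**Figure D3:**
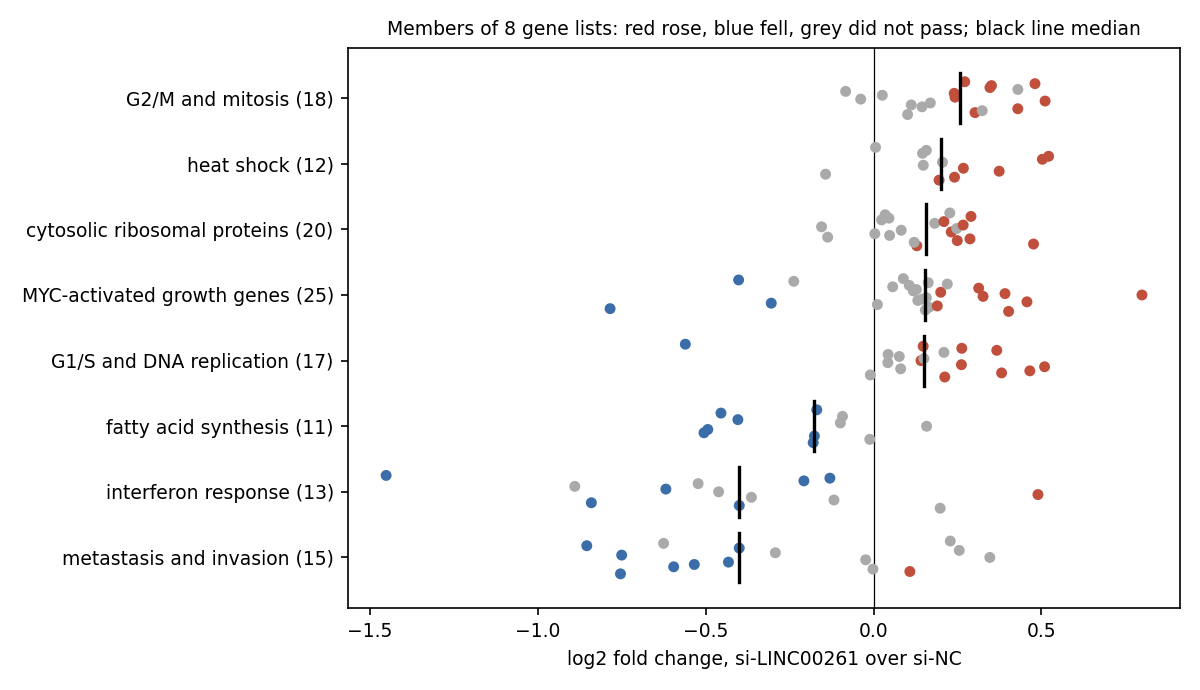
Log2 fold change of si-LINC00261 over si-NC (horizontal axis, n = 3 per group) for each measured member (points) of 8 gene lists (vertical axis, number of measured members in parentheses), with the list median as a black line. The medians run from -0.40 for metastasis and invasion to 0.26 for G2/M and mitosis, and members of each list lie on both sides of 0.

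These 8 lists were those that camera called at the preset correlation, and with a correlation estimated from the data it called 0 of 32 lists. An unadjusted p under 0.05 was then left for 1 list, interferon response. The estimated correlation was -0.008 for interferon response and -0.007 for metastasis and invasion, below the preset 0.01. Their unadjusted camera p still rose, from 0.00433 to 0.0392 and from 0.0105 to 0.0524, so a higher correlation was not the reason there. For the other called lists it ran from 0.10 (ribosomal protein genes) to 0.29 (G1/S). Limma's fry, which does not compare a list with other genes, called 18. Beyond the losses given above, the lists of G1/S, heat shock, ribosomal protein and MYC-activated growth genes lost their calls without si-NC replicate 2 (camera adjusted p = 0.0612, 0.0612, 0.0612 and 0.0712). The same 4 lost them without si-LINC00261 replicate 1 (0.0548, 0.0572, 0.0663 and 0.0663) and without a count filter (0.0646, 0.0643, 0.107 and 0.107). MYC-activated growth genes also lost theirs without si-LINC00261 replicate 2 (0.0854) and without overlapping genes (0.0920). Of the 8 lists, only G2/M kept its call in all 6 fits with a library left out.

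Among the 24 lists that camera did not call, single members changed strongly. Of 16 p53 target genes, 2 rose and 5 fell, both over all genes and when adjusted over the list alone (camera adjusted p = 0.625). CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at -0.97 (SE 0.07), DDB2 at -0.62 (SE 0.10), TNFRSF10B at -0.40 (SE 0.05) and AEN at 0.47 (SE 0.05). Of 16 YAP/TAZ target genes, 7 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.156). These included ANKRD1 (1.21, SE 0.07), CTGF (0.85, SE 0.04), LATS2 (0.75, SE 0.06) and NT5E (-1.11, SE 0.04). Of 12 epithelial marker genes, 4 rose and 2 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.309). ELF3 stood at 0.74 (SE 0.04), OCLN at 0.57 (SE 0.04), KRT19 at -0.55 (SE 0.07) and KRT18 at -0.38 (SE 0.06). Of 12 mesenchymal marker genes, 1 rose and 3 fell (1 and 4 when adjusted over the list alone). Their median was 0.05 and their mean -0.03, and the direction of the test was down (camera adjusted p = 0.586). TNC stood at 0.96 (SE 0.07), TGFBI at -0.65 (SE 0.06), ITGA5 at -0.48 (SE 0.05) and MMP14 at -0.75 (SE 0.13). Of 7 measured regulators of endoderm and pancreas, FOXA1 (1.58, SE 0.15) and ONECUT2 (0.44, SE 0.10) rose and SOX9 (-0.15, SE 0.04) fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.515). FOXA1 was low, at 1.34 ± 0.167 CPM in si-NC and 4.03 ± 0.0509 CPM in si-LINC00261 (SD, n = 3). SOX9 lost its call without any 1 of the 6 libraries (edgeR adjusted p from 0.0527 to 0.103). ONECUT2 lost it without si-NC replicate 1 or si-LINC00261 replicate 1 or 2 (0.0621, 0.0598 and 0.0507). Of 13 glycolysis genes, 1 rose and 6 fell, both over all genes and when adjusted over the list alone (camera adjusted p = 0.166). PKM stood at -0.67 (SE 0.11), HK2 at 0.53 (SE 0.05), PFKP at -0.24 (SE 0.04) and GPI at -0.23 (SE 0.04).

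Markers of other cell types were mostly too low to measure. Past the count filter were 1 of the listed acinar markers, 0 endocrine, 3 fibroblast, 2 immune and endothelial and 1 erythroid marker, too few for a test of these 5 lists. COL1A1 (-0.60, SE 0.03) and CD68 (-0.88, SE 0.19) fell and COL3A1 (0.70, SE 0.08) rose, while PRSS3, THY1, KDR and HBB did not pass. Mitochondrially encoded transcripts took 2.38%, 2.52% and 2.24% of the counts in si-NC and 2.35%, 2.33% and 1.94% in si-LINC00261. Of 12 such genes, 0 rose and 2 fell, both over all genes and when adjusted over the list alone (camera adjusted p = 0.309). Of 12 replication-dependent histone genes, 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.166). Among them were HIST1H2BD (0.31, SE 0.05) and HIST1H1B (0.31, SE 0.06).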

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

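Restricting the test to genes without overlaps, removing the GC and length trends and using table totals without TMM were chosen after seeing the data. LINC00261 kept its fall under every alternative run, with a log2 fold change from -1.58 to -1.48 in the count fits and -0.99 on the log2(FPKM + 1) scale. Leaving aside genes named only as list members, 31 named genes passed, and 26 of these did so under all alternatives that could test them. The other 5 (C9orf69, RN7SK, HSPA8, ENO1 and ACTN4) lost the call under at least 1. Some genes named as list members also lost calls, among them SOX9, ONECUT2, OAS3, IFI6 and TCF7. The count of 4729 genes stayed within 1.5 times, from 3281 to 4781 over the alternatives of filter, scaling, tool and unit. Of the calls, 502 were at least 2-fold. Leaving out each library in turn gave 3271 to 3931 genes, 1526 to 1938 of them higher, the lowest without si-LINC00261 replicate 2 (fewer samples). At least 50 counts per gene left 94 genes that rose and 171 that fell 2-fold (fewer low genes tested), and limma-trend on log2(FPKM + 1), which also changed the filter and the unit, 18 and 22. Without a count filter 39.9% of 4059 calls rose, against 48.8% of 4729. With the replicate block 3472 genes and 7 lists were called, 3355 of these genes in the same direction as without it, and the metastasis and invasion list was lost. Same-numbered libraries did not deviate together (correlations -0.01, 0.01 and 0.02), and 1 of 3 numbers matched best to its own. The 8 called lists became 1 to 7 with a library left out (1 without si-LINC00261 replicate 1, 3 without si-NC replicate 2), 2 without a filter, 5 without overlapping genes, 0 with an estimated correlation and 18 with fry. More lists were also called with the DESeq2 Wald test (10), limma-voom (9) and limma-trend on log2(FPKM + 1) (9). The cause was not tested. The direction reversed only for lists that camera did not call, given as -log10 of the unadjusted p with the sign of the direction. These were ERK/MAPK output -0.164 and immediate early -0.0388 on FPKM, and cholesterol synthesis -0.192 without a filter. NF-kB and inflammatory genes had 0.0531 with the replicate block, 0.217 without a filter, 0.0155 with the trends removed, and -0.152 to 0.118 with a library left out (0.118 and 0.0332 without si-NC replicate 1 or 3, 0.0521 and 0.0152 without si-LINC00261 replicate 1 or 2). Alternatives planned for tables without counts (upper-quartile and quantile scaling, other pseudocounts, limma without a trend or with array weights, and a per-gene test without a shared spread) were not run.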

Other observations

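The siRNA seed test, the control-siRNA test, the tests of GC content and length, of MYC target genes, of REST targets, of fluctuating genes, of sample splits and of RNA types were set before their results were seen. The tests of MYC overlap and MYC noise, the search for the word in LINC00261 transcripts and the per-library checks of RNA types were chosen after the results they bear on had been seen. The medians of the RNA types and the MYC counts of each library had been seen when their tests were set. The results for MYC targets, REST targets and fluctuating genes met the outcomes set in advance as against these explanations. After they were seen, these outcomes were not taken as decisive, so the explanations are left unsettled. Genes of the small RNA pathway, which siRNAs use, changed in both directions. Of 13 genes of this list, AGO2 (-0.28, SE 0.04), DICER1 (-0.62, SE 0.09), AGO1 (-0.24, SE 0.04) and DROSHA (-0.32, SE 0.05) fell and 2, XPO5 (0.29, SE 0.04) and DGCR8 (0.38), rose (5 and 5 when adjusted over the list alone; camera adjusted p = 0.712). Of 10 NRF2 target genes, 0 rose and 4 fell (1 and 4 when adjusted over the list alone, camera adjusted p = 0.156), among them NQO1 (-0.71, SE 0.05), SRXN1 (-0.77, SE 0.06) and GCLM (-0.32, SE 0.06). Camera called the NRF2 list downward with the DESeq2 Wald test (adjusted p = 0.0175) and with limma-trend on log2(FPKM + 1) (0.0142). Of 11 genes of the unfolded protein response of the endoplasmic reticulum, 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0544). They held the chaperone genes HSPA5 at 0.39 (SE 0.03) and DNAJC3 at 0.49 (SE 0.04), PDIA4 at 0.28 (SE 0.04) and HSP90B1 at -0.25 (SE 0.05). The unfolded protein response list was called upward by camera with the DESeq2 Wald test (adjusted p = 0.0175) and limma-voom (0.0251). Of 16 genes of the integrated stress response, 5 rose and 1 fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.156). Among them were PPP1R15A (0.72, SE 0.07), DDIT3 (0.50, SE 0.08), TRIB3 (0.64, SE 0.12) and SLC7A5 (0.28, SE 0.05). Of 9 NF-kB and inflammatory genes, CXCL8 (1.89, SE 0.21) and CXCL1 (1.05, SE 0.15) rose and BIRC3 (-0.85, SE 0.04) fell, with the same counts adjusted over the list alone. Their median was -0.10 and their mean 0.21, and the direction of the test was down (camera adjusted p = 0.993). CXCL8 and CXCL1 were low, with means of 0.802 and 2.79 CPM in si-NC and 2.97 and 5.75 CPM in si-LINC00261.

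The other lists that camera did not call gave these counts over all genes and when adjusted over the list alone. The MYC co-factor network had 5 of 11 genes that rose and 1 that fell (5 and 1, camera adjusted p = 0.1003). CREBBP stood at 0.51 (SE 0.05), MLXIP at 0.32 (SE 0.04) and the MYC antagonist MXD4 at -0.36 (SE 0.06). TGF-beta response genes had 4 of 15 that rose and 6 that fell (4 and 7, camera adjusted p = 0.479), with SMAD6 at -0.88 (SE 0.06) and SKIL at -0.45 (SE 0.05). Of 10 Wnt target genes 1 rose and 3 fell (1 and 3, 0.166), with DKK1 at 0.30 (SE 0.06) and TCF7 at -0.92 (SE 0.23). TCF7 lost its call without si-NC replicate 1 or 3 or si-LINC00261 replicate 1 or 2 (edgeR adjusted p = 0.0693, 0.0703, 0.0739 and 0.0654). Of 12 immediate early genes 3 rose and 1 fell (3 and 1, 0.309), with FOSB at 1.52 (SE 0.22). FOSB was low, with means of 1.16 CPM in si-NC and 3.32 CPM in si-LINC00261, and overlaps ERCC1. Of 12 hypoxia genes 1 rose and 4 fell (1 and 4, 0.479), with EGLN1 at -0.40 (SE 0.06). Of 16 apoptosis regulators 2 rose and 3 fell (2 and 3, 0.309), with BAK1 at -0.52 (SE 0.10). Of 16 cholesterol synthesis genes 2 rose and 1 fell (2 and 1, 0.515; median 0.05, mean -0.02, test direction up), with STARD4 at -0.59 (SE 0.10). Of 12 ERK output genes 2 rose and 1 fell (2 and 1, 0.679; median -0.01, mean 0.10, test direction up), with DUSP5 at 0.46 (SE 0.07). Of 21 proteasome genes 4 rose and 1 fell (4 and 1, 0.309), with PSMB5 at -0.67 (SE 0.06). Of 22 nuclear respiratory chain genes 2 rose and 3 fell (2 and 3, 0.515), with NDUFS1 at -0.31 (SE 0.03). Of 17 lysosome and autophagy genes 5 rose and 4 fell (5 and 4, 0.549), with SQSTM1 at -0.52 (SE 0.06).

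Genes whose 3' UTR carries the heptamer CCATTCA were lower than other genes in the si-LINC00261 libraries, and off-target seed pairing of the LINC00261 siRNA may account for part of the genes that fell. The z of CCATTCA was -8.21, below the lowest z of 100 permutations (-4.89). Median log2 fold changes were -0.12 over 1113 genes with 1 site and -0.19 over 182 genes with 2 or more, against 0.00 over 10151 without. Carriers made up 21.2% of 212 genes that fell at least 2-fold and 10.3% of genes not called (Fisher's exact test p = 4.20e-06, not adjusted for UTR length). The word was picked as the lowest of 15661 on these same fold changes. The medians by site number and the Fisher test therefore describe it and are not separate support. The overlapping words CATTCAA (-6.64) and ACCATTC (-4.50) ranked next, the latter within the range of the permutations. They share most of their bases with CCATTCA, so they are not separate support. CATTCAA carriers were 12.3% of genes that fell at least 2-fold and 9.50% of genes not called (Fisher's exact test p = 0.191). The reverse complement TGAATGG had a z of -0.76. Carriers of CCATTCA were lower in each si-LINC00261 library, each set against the same si-NC mean (by -0.10, -0.09 and -0.11 after adjustment). A seed effect in all of these libraries would require a shared seed, and whether they received the same siRNA is not given. In the 3' UTR scanned for each gene, NDRG2 and SAMD12 carry a site and TRIM32, REST and AMPD3 do not. Of the 212 genes that fell at least 2-fold, 167 lack a site there. Other 3' UTRs of these genes were not scanned. Genes without a site are left to an effect of LINC00261 loss, to indirect effects or to other pairing, which were not told apart. CCATTCA occurs in 1 of 3 annotated LINC00261 transcripts, as do 26.6% of all words in at least 1 of them. A microRNA released from LINC00261 and an siRNA strand complementary to LINC00261 would both go with such a site. Its presence therefore cannot tell them apart. For genes that rose, the highest z was 5.05 (TCGGAGA, highest permuted 4.41). Its carriers were 3.07% of genes that rose at least 2-fold and 1.74% of genes not called (Fisher's exact test p = 0.215). This leaves release from seed pairing of the control siRNA open.

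MYC differed between libraries of the same group by more than genes of like level, with a within-group SD of 1.67 on the log2 scale against a median of 0.19 over 500 such genes (percentile 99.6), which argues against counting noise at a low level. Reads shared with overlapping genes are argued against by 0 GENCODE genes, and 0 genes with a mean of 10 or more counts, whose locus overlaps MYC. A change in MYC activity between the libraries was examined through MYC-activated growth genes. MYC was higher by 3.19 on the log2 scale in si-LINC00261 replicates 2 and 3 than in replicate 1. Between these libraries 25 MYC-activated growth genes had a median difference of -0.01, at percentile 34.8 of 10000 random lists of like level. Most random lists lay between -0.046 and 0.031. These growth genes therefore showed no shift with MYC as a group, the outcome set in advance as speaking against a change in MYC activity. The comparison rests on replicate 1 alone on its low side, so a change in MYC activity is left unsettled. How the authors' counting split reads among MYC transcripts was not tested.

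Processed pseudogenes rose more often than they fell (82 and 14 of 906, median log2 fold change 0.24), while sense intronic RNAs (2 and 21 of 266, median -0.18) and RNAs to be experimentally verified (5 and 29 of 228, median -0.13) fell more often. GC content and length bias is argued against as the whole cause, since 78.5% of the pseudogene median and 96.2% of the sense intronic median were kept with the trends removed. A lower share of unspliced RNA in the si-LINC00261 libraries is a candidate explanation for the intronic part, but not a settled one. Sense intronic RNAs were lower than their host genes by a median of -0.19 (154 of 222 lower, two-sided exact sign test p = 7.64e-09). This difference shrank to -0.06 without si-NC replicate 2 (128 of 222, two-sided exact sign test p = 0.0265), where these RNAs were highest. The sign test counts RNAs of the same libraries as separate, so its p does not measure the spread between libraries. Against the si-NC mean, the sense intronic median was -0.05, 0.16 and -0.10 in si-NC replicates 1 to 3. It was -0.09, -0.16 and -0.13 in si-LINC00261 replicates 1 to 3, so the groups overlapped. The pseudogene median was 0.12 without si-LINC00261 replicate 3, where it was 0.40 against 0.14 in each of the other 2, and without si-NC replicate 2 the sense intronic median was -0.07 and that of RNAs to be experimentally verified -0.08; with a library left out 46 to 76 pseudogenes rose and 7 to 17 fell, and 0 to 2 sense intronic RNAs rose and 10 to 17 fell. Reads shared with parent genes cannot be told apart from a change of the pseudogenes themselves, as the fold changes of 468 pairs correlated across genes with a Spearman rho of 0.155 (permutation p = 0.0011), between the bounds set in advance.

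With the GC and length trends removed, 93.1% of the 4729 calls were kept in the same direction and 7 of the 8 list calls remained, without the ribosomal protein list (camera adjusted p = 0.0793). The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4729 genes and 8 lists, and no other split reached either (1 of 10 each, the real one). Among the others the highest counts were 4 genes and 6 lists, in different splits. The split with 6 lists called 0 genes, and another called 5 lists and 0 genes. Camera at the preset correlation thus called several lists in groupings where no gene passed. REST target genes fixed beforehand did not rise as a group: of 28 measured, 3 rose and 8 fell (3 and 8 when adjusted over the list alone), with a median of -0.16 and a camera p of 0.126 in the downward direction (p = 0.267 with an estimated correlation). CELSR3 (0.75, SE 0.05) and BDNF (0.78, SE 0.07) rose and CACNA1H (-0.68, SE 0.06) fell. The list did not go up, which was set in advance as the outcome against a release of REST target genes. Its camera p does not set the list apart from other genes, so a release of part of the targets is not decided. Of the 500 genes that varied most within groups, 47.8% overlapped another gene, against 40.8% of the others (odds ratio 1.33, 95% interval 1.11 to 1.59, Fisher's exact test p = 0.00196). The odds ratio lay under the bound set in advance for reads shared with overlapping genes, but its interval reached past that bound.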
